A study of Danio rerio with 246 samples.

How the data were processed

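Single cells of the adult zebrafish kidney marrow were sorted by fluorescence into 96-well plates and amplified with a modified Smart-seq2 protocol, per the labels. Each of the 246 samples used here is 1 cell of 1 of 6 reporter lines, named in its title with plate and well. The deposited table gives counts of reads per Ensembl gene and cell. The submitters' processing notes name STAR, Picard and featureCounts with genome build GRCz10, without versions or the order of steps. The values are whole numbers, and both the reads and the detected genes per cell in the cell table equal those of the count table in all 246 cells. Per the file headers, a mapping table gives the percent of uniquely mapped and multimapped read pairs, and the fraction of PCR duplicates, per well. It holds 384 wells, of which 138 have no cell in the count table and were not used. The labels name no molecular identifiers, so reads amplified by PCR are not independent molecules, and every interval and floor covers counting error only. Droplet data of the same series were not used here.

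The count table holds 21876 genes, of which 425 have no read. Of these genes 2527 have no symbol in the table, with 5.23% of all reads, and they count in totals but not in lists. Median reads per cell were 877541 (Runx123_GFP), 1090375 (cd41_GFPlow), 457962 (mpx_EGFP), 704023 (rag2_GFP), 667513 (lck_GFP) and 1218459 (lck_GFP_rag1). Median uniquely mapped read pairs were 76.5, 83.2, 81.6, 65.2, 63.6 and 73.6% in the same order, and median PCR duplicates were 16.9, 17.4, 15.3, 13.8, 16.1 and 27.9%. Median reads on mitochondrial messenger RNA genes were 1.11 to 2.73%, with 54.1% in 1 lck_GFP_rag1 cell. No cell was left out of the main values.

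Counts were summed over the cells of a line and scaled to counts per 1000000 (CPM) of the line's sum. A difference was log2((CPM a + 1)/(CPM b + 1)), with a pseudocount of 1 CPM. The reference of 1 line against the others was the unweighted mean CPM of the other 5 lines. A gene high in 1 of these raises the mean, so a lower call can reflect that line alone. A list gene counted as measured at 10 CPM in at least 1 line compared, and as higher or lower at an absolute log2 ratio of at least 2, which is 4-fold. Each line is 1 sample, so these counts are descriptions by size and no p-value was made from cells. Summed counts have 95% exact Poisson intervals, and folds between lines have exact intervals from the same counts. A fold against 0 reads is a lower bound against a floor of 3 reads, over the other 5 lines for a line against the others and in the other line for a pair. A list median was also given with such genes at their bounds, and as a percentile among 10000 random lists of the same size matched on mean expression in 20 bins. The 3 pairs compared were Runx123_GFP with cd41_GFPlow, lck_GFP with lck_GFP_rag1, and lck_GFP with rag2_GFP.

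The comparisons, lists, size rule and naming rule and the alternatives tried, save those named later, were set before the data were examined. The 17 lists were stem and progenitor (HSPC), thrombocyte, erythroid, neutrophil, monocyte and macrophage, B cell, T cell, NK and cytotoxic, shared T and NK, eosinophil, class II presentation, joining of antigen receptor segments, cell cycle, kidney tubule and podocyte, endothelial, stroma, and immediate early and stress genes. They do not hold itga2b, lck, rag1, rag2 or runx1. The eosinophil list holds epx, and whether that is the gene otherwise called mpx was not settled. Of 251 list entries 222 matched a gene of the table, 34 of them by symbol without its last letter or number and 9 by another symbol of the same gene, and 29 did not match. The ways of matching were chosen after the table was seen. So was the choice of the counts and shares that answer each comparison. The gene epx was shown beside the reporter genes after its values were seen, and the table holds it under 2 identifiers, the second at 3.39 CPM in mpx_EGFP.

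Genes were named by a fixed rule. For each line against the others the 10 largest log2 ratios were named, and for each pair the 10 largest in each direction. A named gene reached 10 CPM in at least 50% of the cells of the higher line, had a summed CPM of at least 50 there, a log2 ratio of at least 2, and a symbol that is not a clone name. List genes and reporter genes were named as well.

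A cell had a list when at least 3 of its genes were at 10 CPM or more in that cell. Shares of cells have exact Clopper-Pearson 95% intervals, and a share of 0 has the limit of 3 cells of the total. This limit lies below the exact upper bound, which is 8.22% for 0 of 43 cells. Shares were repeated with each cell thinned at random to 200000 reads, the largest planned depth that kept at least 80% of the cells of every line (36, 43, 47, 41, 32 and 30 cells in the order above). Clusters came from log(CPM + 1) of the 2000 most variable genes among those with a read in at least 5 cells, 15 principal components, 10 neighbours and Leiden at resolution 1 with a fixed seed. A cluster took the name of the list with the most markers, at least 3, present in at least 25% of its cells and 4-fold above the other cells, unless another list held more of its 10 top genes. That naming rule was set after the data were seen, and only its markers were fixed before.

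The alternatives were TMM and DESeq2 scaling, the mean of per-cell CPM, removal of the deepest cell per line, cells of at least 1000 detected genes, other pseudocounts, size rules and filters, thinning, other marker thresholds and other clusterings. A further pair, without cells under 50% uniquely mapped and without each gene's top cell in each line, was chosen after seeing the data. The size rule was tested on simulated data, with Poisson counts alone. All cells of a line came from 1 mean profile, so passes that come from single cells were not simulated. In each of the 3 pairs, 0 of 50 genes changed 2-fold and 0 unchanged genes passed the rule. The changed genes all rose, so scaling to the sum lowered every ratio. Unchanged genes had medians of -0.61, -0.68 and -0.91 (log2) in the order of the pairs above, and genes changed 2-fold 0.38, 0.31 and 0.08. Of 50 genes changed 8-fold, 50 passed in Runx123_GFP with cd41_GFPlow and in lck_GFP with lck_GFP_rag1, and 47 in lck_GFP with rag2_GFP. All 50 genes passed at 16-fold and at 32-fold in each pair. A list of 20 genes changed 8-fold stood at percentile 99.98, 100 and 100 in these pairs. In 80 simulated cells of a pair of uniform groups, with 200 genes changed 8-fold between them, clustering gave 4 clusters and 0 cells in a mixed cluster. It kept the groups apart but also split cells drawn from the same profile. Python 3.11.15 was used with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, scanpy 1.11.5, leidenalg 0.10.2, scikit-learn 1.9.0 and matplotlib 3.10.9, and R 4.3.3 with edgeR 4.0.16 and DESeq2 1.42.0.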

Results

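The data were reads from 246 single cells of the whole kidney marrow, the blood-forming organ of adult zebrafish, sorted from 6 fluorescent reporter lines. The lines gave 39 cells (Runx123_GFP), 43 cells (cd41_GFPlow), 47 cells (mpx_EGFP), 48 cells (rag2_GFP), 38 cells (lck_GFP) and 31 cells (lck_GFP_rag1). Each cell had 47630 to 2969770 assigned reads and 516 to 4901 detected genes. Summed reads per line ranged from 23028484 in lck_GFP to 47836984 in cd41_GFPlow. The median cell had 2295 detected genes in Runx123_GFP, 2804 in cd41_GFPlow and 1606 in mpx_EGFP. The lymphoid reporters had fewer, with medians of 782 in rag2_GFP, 925 in lck_GFP and 1065 in lck_GFP_rag1. After thinning to equal reads the order of the 3 non-lymphoid medians was the same, at 2096, 2463 and 1495 genes, and the lymphoid medians were 691, 831 and 808. The labels name no animals, so each line is 1 sample, no p-value was made between lines, and the intervals cover counting of reads or cells but not differences between animals. Line and plate were the same division of the cells except on plate 2, which held rag2_GFP and lck_GFP.

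The genes that the reporters are named after came first, as a check of the labels. The kinase gene lck, which acts in T cell receptor signalling, was at 853 counts per 1000000 reads (CPM; 95% exact Poisson interval 842 to 865) in the summed profile of lck_GFP and at 675.0 CPM (667 to 683) in that of lck_GFP_rag1. It reached 10 CPM in 30 of 38 lck_GFP cells (78.9%; exact Clopper-Pearson interval 62.7 to 90.5%, 81.2% after thinning) and in 16 of 31 lck_GFP_rag1 cells (51.6%; 33.1 to 69.8%, 53.3% after thinning). Elsewhere lck was at most 56.5 CPM, in mpx_EGFP. The recombinase genes rag2 and rag1, which cut antigen receptor loci, were at 283 CPM (277 to 289) and 326 CPM (320.1 to 333) in rag2_GFP, from 6 and 3 of its 48 cells. Mean per-cell CPM put rag1 there at 633 CPM. In lck_GFP neither recombinase gene had a read, and in cd41_GFPlow both came from 1 cell each, at 105.4 CPM for rag2 and 156 CPM for rag1. The integrin gene itga2b, also called cd41, was at 1595 CPM (1582 to 1608) in Runx123_GFP, in 15 of 39 cells (38.5%; 23.4 to 55.4%, 36.11% after thinning), and it was at 2509 CPM after thinning and 3014 CPM as the mean of per-cell CPM. In cd41_GFPlow, the line that carries its name, itga2b had 15 reads (0.314 CPM) and reached 10 CPM in 0 of 43 cells. This allows a share of up to 6.98% (exact upper bound 8.22%). The transcription factor gene runx1 was low in every line, at 1.31 CPM in Runx123_GFP, 4.04 CPM in cd41_GFPlow and at most 9.09 CPM, in rag2_GFP. After thinning, runx1 in Runx123_GFP was at 2.78 CPM. The symbol mpx was not among the gene names used here, and whether a gene named epx is the one otherwise called mpx was not settled. The peroxidase gene epx reached 10 CPM in all 47 mpx_EGFP cells, at 4361 CPM (4335 to 4388), and in 9 of 43 cd41_GFPlow cells, at 1100.0 CPM. Values of this gene in the other lines were at most 0.174 CPM, and a second gene named epx was at most 3.39 CPM, in mpx_EGFP. The transgenes themselves were not analysed here.

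Cells of the Runx123_GFP line carried erythroid and thrombocyte transcripts, and some of the stem and progenitor list, at higher levels than the mean of the other lines. Erythroid genes were raised as a whole list, thrombocyte genes in large part, and mature white blood cell genes were low. All 15 measured erythroid list genes were at least 4-fold higher in Runx123_GFP than in the mean of the other 5 lines. Among them, the alpha globin genes hbaa1 and hbaa2 were at 1075 and 2280 CPM against means of 14.7 and 4.98 CPM. The haem synthesis gene alas2 was at 893 CPM against 4.61 CPM. Of 12 measured thrombocyte list genes, 8 were higher and 2 lower. With a filter of 50 CPM 5 were higher, and in cells of at least 1000 genes 1 was lower. The gene gp1bb, which encodes a subunit of the receptor for von Willebrand factor, was at 1066 CPM (1055 to 1077) against 0.529 CPM. The stem and progenitor list had 5 of 12 genes higher and 1 lower, cebpa, a myeloid transcription factor gene. Its tal1, which directs early blood formation, was at 764 CPM against 9.66 CPM, and meis1 was at 521 CPM against 9.81 CPM. Of 23 cell cycle genes, 10 were higher and 0 lower, among them rrm1 at 329 CPM against 31.4 CPM. The count of higher cell cycle genes was 6 in cells of at least 1000 genes and 18 without each gene's top cell in each line, an alternative chosen after the results were seen. The list medians were 4.71 (log2) for erythroid, 5.20 for thrombocyte (7.17 at the bounds of genes with 0 reads), 1.60 for stem and progenitor and 1.93 for cell cycle genes, at percentile 99.99 of random lists for stem and progenitor genes and 100 for the others. All 14 neutrophil genes and all 16 T cell genes were lower. Named by size were also tgm2, tubb1, hdr, zfpm1, znfl2a, rhag, nfe2 and gata1a, with log2 ratios of 4.71 to 6.83.

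The cd41_GFPlow cells stood out by monocyte and macrophage genes. Thrombocyte genes were mostly below the mean of the other lines, which Runx123_GFP raised, and the stem and progenitor list was mixed. Summed over the thrombocyte list, Runx123_GFP had 4376 CPM, cd41_GFPlow 1072 CPM and the other lines at most 487 CPM, in mpx_EGFP. Of 16 measured monocyte and macrophage genes, 12 were higher than in the mean of the other lines and 1 was lower, with a median log2 ratio of 3.07 (3.08 at the bounds). The complement genes c1qa, c1qb and c1qc, which mark tissue macrophages, were at 190 CPM (186 to 193), 405 CPM (400.0 to 411) and 301 CPM (296 to 306), against means of 11.8, 19.6 and 21.4 CPM. The scavenger receptor gene marco was at 415 CPM against 40.5 CPM, and it reached 10 CPM in 5 of 43 cells. Of 12 thrombocyte genes, 8 were lower, among them mpl, the thrombopoietin receptor gene, with 0 reads, and 2 were higher, f13a1b at 634 CPM and a gene named fn1 at 227 CPM. Of 12 stem and progenitor genes, 2 were higher and 3 lower, and the list median of -0.29 lay at percentile 39.5 of random lists. Without each gene's top cell in each line, 1 was higher and 5 were lower. The higher pair was gata2b, at 50.6 CPM against 4.21 CPM, and kit, at 12.6 CPM against 1.97 CPM. The 10 genes named by size included s100a10b, which encodes a calcium-binding family member, at 1245 CPM against 20.02 CPM. They also included the class II antigen presentation gene mhc2dab, at 789 CPM against 68.5 CPM, and the chemokine receptor gene cxcr3.2, at 465 CPM against 51.7 CPM. The detoxification gene gsta.1 was at 58.0 CPM and had 0 reads in the other 5 lines, at least 3042-fold higher against a floor of 3 reads over those lines. Ratios for the other 6 named genes ran from 2.26 to 4.93 on the log2 scale, and the lowest, ctsd, was 1.96 with DESeq2 size factors.

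Neutrophil genes were high in mpx_EGFP. Those for a secreted metalloprotease and for lysozyme, which acts against microbes, were among its most abundant. Of 14 measured neutrophil genes, 12 were higher than in the mean of the other lines and 0 lower, with a median log2 ratio of 4.53. The genes npsn, which encodes a secreted metalloprotease, and lyz, for lysozyme, were at 33043 CPM (32970 to 33116) and 18927 CPM (18872 to 18983), against 601 and 605 CPM. Each of them reached 10 CPM in all 47 cells. The collagenase gene mmp13a was at 2942 CPM (2920 to 2964) against 2.26 CPM, in 37 of 47 cells. The myeloid factor gene cebpa, of the stem and progenitor list, was at 2307 CPM against 251 CPM, while 8 of the 12 genes of that list were lower. Immediate early genes had a median log2 ratio of 1.01, with 3 of 13 genes higher and 2 lower, and 6 were higher without each gene's top cell in each line. Named by size beside mmp13a were slc51a, a transporter gene with 1 read in the other lines together and 380 CPM here, the actin regulator gene cfl1l at 1334 CPM, the chitinase gene chia.6 at 863 CPM and gapdh at 1033 CPM. The other 5 named genes had log2 ratios of 5.85 to 7.65.

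B cell transcripts set rag2_GFP apart. Genes of the antigen receptor and its signalling chain were raised, with none of the B cell list lowered. Of 14 measured B cell genes, 12 were higher than in the mean of the other lines, with a median log2 ratio of 6.68. The heavy chain gene ighm was at 2047 CPM (2032 to 2063) against 28.95 CPM, and the receptor chain gene cd79a at 709 CPM (699 to 718) against 13.7 CPM. The B cell regulator gene pax5 was at 323 CPM with 0 reads elsewhere, at least 18651-fold higher against 3 reads over the other lines. The tetraspanin gene cd37 was at 2445 CPM (2428 to 2462) against 0.812 CPM. Named by size were also cd79b, at 747 CPM with 2 reads elsewhere, plaat1l, at 1835 CPM with 3 reads elsewhere, and 7 light chain genes. The light chain gene igic1s1 was at 405 CPM with 0 reads elsewhere. Values of single light chain genes are uncertain, because near-identical copies may share reads. Class II presentation genes cd74a and cd74b were at 5600.0 and 2874 CPM against 864 and 522 CPM, in a list with 3 of 8 genes higher and 2 lower. In cells of at least 1000 detected genes, 10 of rag2_GFP, none of that list was higher and 4 were lower. Some genes of the myeloid lists were also high, namely mpeg1 at 767 CPM in 17 of 48 cells and ncf1, an oxidase subunit gene, at 1900.0 CPM in 26 of 48 cells. Most of these lists was low, with 1 of 14 neutrophil genes higher and 12 lower. Of 16 monocyte and macrophage genes, 1 was higher and 14 were lower. The list for joining of antigen receptor segments had 2 of 5 genes higher and 1 lower, each in at most 2 cells, and 1 was higher and 2 lower without the cell with the most reads in each line.

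T cell transcripts were high in lck_GFP. The co-receptor, cytokine receptor and signalling genes of T cells were raised across the list. Of 16 measured T cell genes, 14 were higher than in the mean of the other lines and 2 lower, with a median log2 ratio of 5.92 (6.34 at the bounds). The cytokine receptor gene il7r, needed for T cell survival, was at 1367 CPM (1352 to 1382) against 1.86 CPM. The chemokine receptor gene ccr9 was at 2817 CPM (2796 to 2839) against 98.4 CPM, and themis, which acts in thymic selection, at 1017 CPM (1004 to 1030.0) against 43.95 CPM. The kinase gene itk was at 512 CPM with 0 reads elsewhere, at least 31050-fold higher against 3 reads over the other lines. The co-receptor genes cd4-1 and cd8a were at 445 CPM in 8 cells and 128 CPM in 6 cells. The lower pair was gata3 and a second gene named ccr9, both with 0 reads here, and none was lower without each gene's top cell in each line. Of 9 genes shared by T and natural killer (NK) cells, 4 were higher and 1 lower, the kinase gene jak3. Also named by size were ccr7, spint1a, rrp8, shisa10.2, sash3, stk17al and mhc1uba, with log2 ratios of 3.42 to 8.34, and mhc1uba is uncertain for its similar copies.

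In lck_GFP_rag1 the raised genes were those of NK and cytotoxic cells. Killer proteins, chemokines and immune-type receptors made up most of the list. Of 37 measured NK and cytotoxic genes, 29 were higher than in the mean of the other lines and 5 lower, with a median log2 ratio of 4.20 (4.42 at the bounds). The granulysin-like gene nkl.2 was at 1279 CPM (1269 to 1290.0) against 0.0356 CPM. The chemokine gene ccl36.1 was at 4930.0 CPM (4909 to 4951) against 60.5 CPM, and il2rb, a cytokine receptor gene of killer cells, at 742 CPM (733 to 749.7) against 16.9 CPM. The transcription factor gene tbx21 was at 190.0 CPM against 5.56 CPM. Members of the nkl, ccl and nitr families are uncertain where similar copies share reads. Of 16 T cell genes 13 were lower, and of 23 cell cycle genes 14 were lower. Without each gene's top cell in each line the lower NK and cytotoxic genes were 3 and the lower cell cycle genes 22. Of the 9 genes shared by T and NK cells, 4 were higher, among them sla2b and txk at 391 and 208 CPM, and 1 was lower, zap70, with 0 reads. Of 8 class II genes, 0 were higher and 0 lower. Also named by size were zbtb32, ccl38.6, lamp3, dock10, tnip1, glrx and wipf1, with log2 ratios of 2.31 to 7.20.

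**Figure D1:**
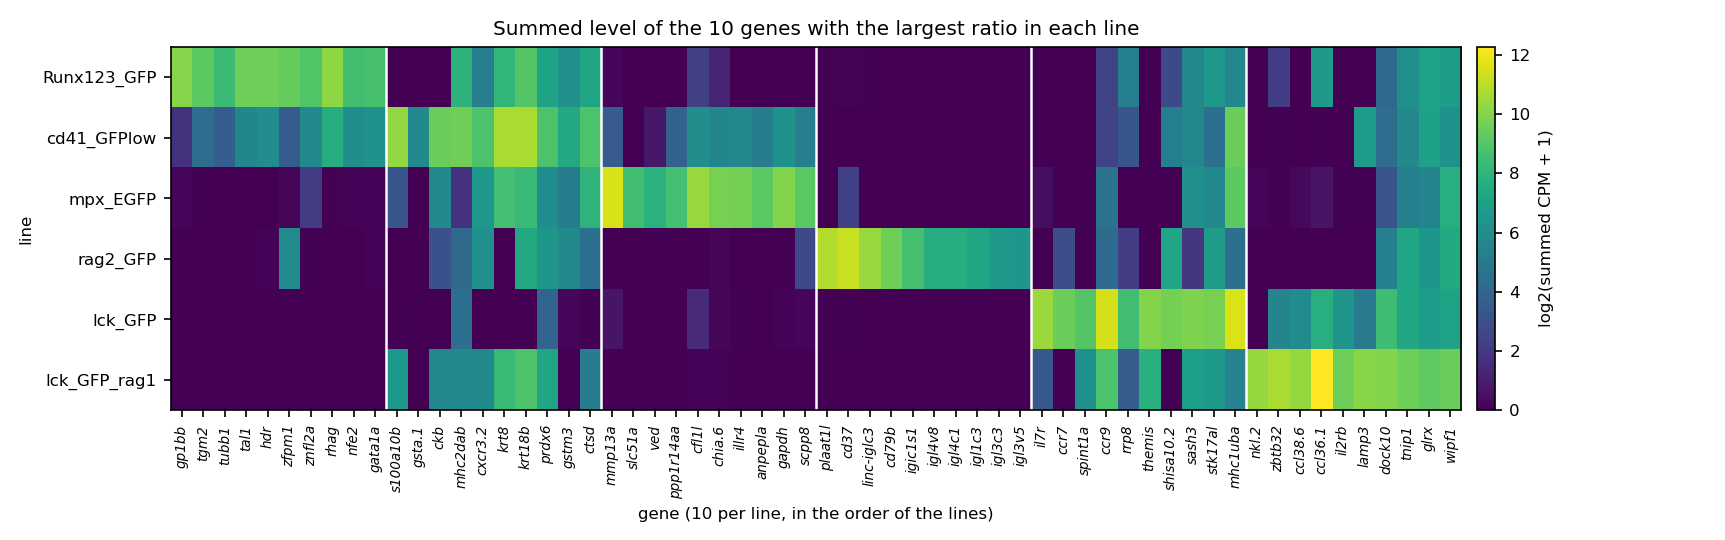
Heat map of log2(summed CPM + 1) for the 10 genes named by size in each line (columns) in the 6 lines (rows). The values of a line's own 10 genes are highest in that line, for example 1066 CPM of gp1bb in Runx123_GFP and 1279 CPM of nkl.2 in lck_GFP_rag1.

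Between Runx123_GFP and cd41_GFPlow, Runx123_GFP had the erythroid and thrombocyte genes and cd41_GFPlow the myeloid ones. In Runx123_GFP, 13 of 15 erythroid genes were at least 4-fold higher than in cd41_GFPlow and 0 lower (median log2 ratio 2.77), and the count was 7 under an 8-fold rule. Of 11 thrombocyte genes, 8 were higher and 2 lower (median 4.92, 8.27 at the bounds), and 5 were higher with a filter of 50 CPM. The gene gp1bb was 432-fold higher (361 to 522), and mpl was at least 13729-fold higher against 3 reads. Of 12 stem and progenitor genes, 6 were higher and 1 lower (median 1.90). Among these, tal1 was 15.8-fold higher (15.2 to 16.5) and lmo2, its binding partner, 9.20-fold higher (8.76 to 9.67). This list is not particular to progenitors, since lmo2 was also at 766 CPM in rag2_GFP. The lower gene was cebpa, at 126 CPM against 1000 CPM, and myb was near even at 290 and 260 CPM. Of 13 neutrophil genes 12 were lower in Runx123_GFP (median -3.87), as were 12 of 14 monocyte and macrophage genes (median -6.60, -9.19 at the bounds) and 5 of 8 class II genes. Higher in cd41_GFPlow by size were s100a10b, at least 14869-fold, alox5ap, for a leukotriene synthesis protein, at least 3593-fold, and cebpb, a myeloid factor gene, 17.1-fold (16.04 to 18.3). The plates of these lines differ.

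Between the lck reporters, lck_GFP had T cell genes and lck_GFP_rag1 had NK and cytotoxic genes. Recombination of antigen receptors needs rag1, and the labels do not state the genotype that its name stands for in lck_GFP_rag1. In lck_GFP, 13 of 14 T cell genes were higher and 0 lower (median log2 ratio 6.47, 8.28 at the bounds). With cells of at least 1000 detected genes, 12 in lck_GFP and 18 in lck_GFP_rag1, 8 were higher. The genes cd4-1, cd8a, bcl11ba and itk had 0 reads in lck_GFP_rag1, and itk was at least 7296-fold higher in lck_GFP. The gene il7r was 153-fold higher (138 to 169.8). In contrast, ccr9 and themis were present in lck_GFP_rag1, at 439 and 220 CPM in 5 of 31 cells each. Of 33 NK and cytotoxic genes, 27 were lower in lck_GFP and 2 higher (median -5.02, -7.13 at the bounds), with 1 higher without the cell with the most reads in each line. In lck_GFP_rag1, nkl.2 was at least 9820-fold higher against 3 reads, zbtb32, a transcription factor gene, 34.8-fold higher (32.8 to 36.98), and ccl36.1 24.3-fold higher (23.6 to 25.1). The receptor kinase gene zap70 was at 883 CPM in lck_GFP and had 0 reads in lck_GFP_rag1, and jak3 was at 4.69 CPM in lck_GFP and 467 CPM in lck_GFP_rag1. All 14 measured monocyte and macrophage genes were higher in lck_GFP_rag1, and 93.4% of the reads of that list came from 1 cell. Without the cell with the most reads in each line the count was 2. A pair of named genes depended on processing, il2rb with a log2 ratio of 1.97 after thinning and glrx with 1.59 in cells of at least 1000 genes. Plate and line cannot be told apart here.

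Between the reporters on plate 2, lck_GFP had T cell and shared T and NK genes, and rag2_GFP had B cell genes. All 14 measured T cell genes were higher in lck_GFP (median log2 ratio 7.08, 9.61 at the bounds), and all 14 B cell genes were lower (median -8.80, -11.23 at the bounds). The gene il7r was at least 14443-fold and themis at least 10746-fold higher in lck_GFP against 3 reads, and lck itself was 51.2-fold higher (46.99 to 55.97). In rag2_GFP, cd79b was at least 5735-fold higher against 3 reads, and the oxidase subunit gene cyba 2593-fold higher (1258 to 6450.0). Of 9 genes shared by T and NK cells, 7 were higher in lck_GFP and 2 lower, or 1 lower in cells of at least 1000 genes. Of 12 NK and cytotoxic genes, 9 were higher and 3 lower, and the former included ccl36.1 at 202 CPM. In lck_GFP 62.2% of the reads of that list came from 1 cell, and without each gene's top cell in each line 5 were higher and 0 lower. Of 7 class II genes 5 were lower in lck_GFP, and 2 in cells of at least 1000 genes.

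The share of cells with at least 3 genes of a list at 10 CPM or more was highest, for each of 8 cell type lists, in the line with that list's genes raised. Neutrophil genes met this in 47 of 47 mpx_EGFP cells (100%; interval 92.4 to 100%, 100% after thinning) and in 21 of 43 cd41_GFPlow cells (48.8%; 33.31 to 64.5%, 48.8% after thinning). With at least 5 genes the cd41_GFPlow share was 16.3%, and with any read as presence 79.1%. B cell genes met it in 45 of 48 rag2_GFP cells (93.8%; 82.8 to 98.7%, 95.1% after thinning) and in 5 of 43 cd41_GFPlow cells (11.6%; 3.89 to 25.1%, 11.6% after thinning). T cell genes did so in 35 of 38 lck_GFP cells (92.1%; 78.6 to 98.3%, 93.8% after thinning), a share of 52.6% with at least 5 genes, and in 0 of 31 lck_GFP_rag1 cells, which allows up to 9.68% (exact upper bound 11.2%). NK and cytotoxic genes did so in 27 of 31 lck_GFP_rag1 cells (87.1%; 70.17 to 96.4%, 90% after thinning). They also did so in 24 of 47 mpx_EGFP and 17 of 43 cd41_GFPlow cells (53.2% and 41.9% after thinning), where fcer1gl, a receptor adaptor gene, was at 1941 and 781 CPM. Stem and progenitor genes reached 3 in 32 of 39 Runx123_GFP cells (82.1%; 66.5 to 92.5%, 83.3% after thinning) and in 23 of 43 cd41_GFPlow cells (53.5%; 37.6 to 68.8%, 55.8% after thinning). With at least 5 genes these shares were 38.5% and 9.30%. The mpx_EGFP line also reached 3, in 13 of 47 cells (27.7%; 15.6 to 42.6%, 31.9% after thinning). The commonest genes of that list in cd41_GFPlow, cebpa in 31 cells and myb in 23, were also in 44 and 19 mpx_EGFP cells, so its share is not specific to progenitors. The Runx123_GFP share is not specific either. Of that list, 6 genes marked the thrombocyte-like cluster, made only of Runx123_GFP cells, and 4 marked the HSPC-like cluster. Its lmo2 was also in 18 of 48 rag2_GFP cells, at 766 CPM. Erythroid genes reached 3 in 20 of 39 Runx123_GFP cells (51.3%; 34.8 to 67.6%, 52.8% after thinning) and 6 of 43 cd41_GFPlow cells (13.95%; 5.30 to 27.9%, 11.6% after thinning). Thrombocyte genes did in 16 of 39 Runx123_GFP cells (41.03%; 25.6 to 57.9%, 38.9% after thinning), a share of 20.5% with at least 5 genes, and 7 of 43 cd41_GFPlow cells (16.3%; 6.80 to 30.7%, 16.3% after thinning). In cd41_GFPlow the commonest genes of that list were f13a1b in 19 cells, a gene named sele in 14, which was also in 26 mpx_EGFP cells, and a gene named fn1 in 11, while mpl and gp9 were in 0 and gp1bb in 2. Monocyte and macrophage genes did in 15 of 43 cd41_GFPlow cells (34.9%; 21.01 to 50.9%, 34.9% after thinning) and 53.5% with at least 2 genes.

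**Figure D2:**
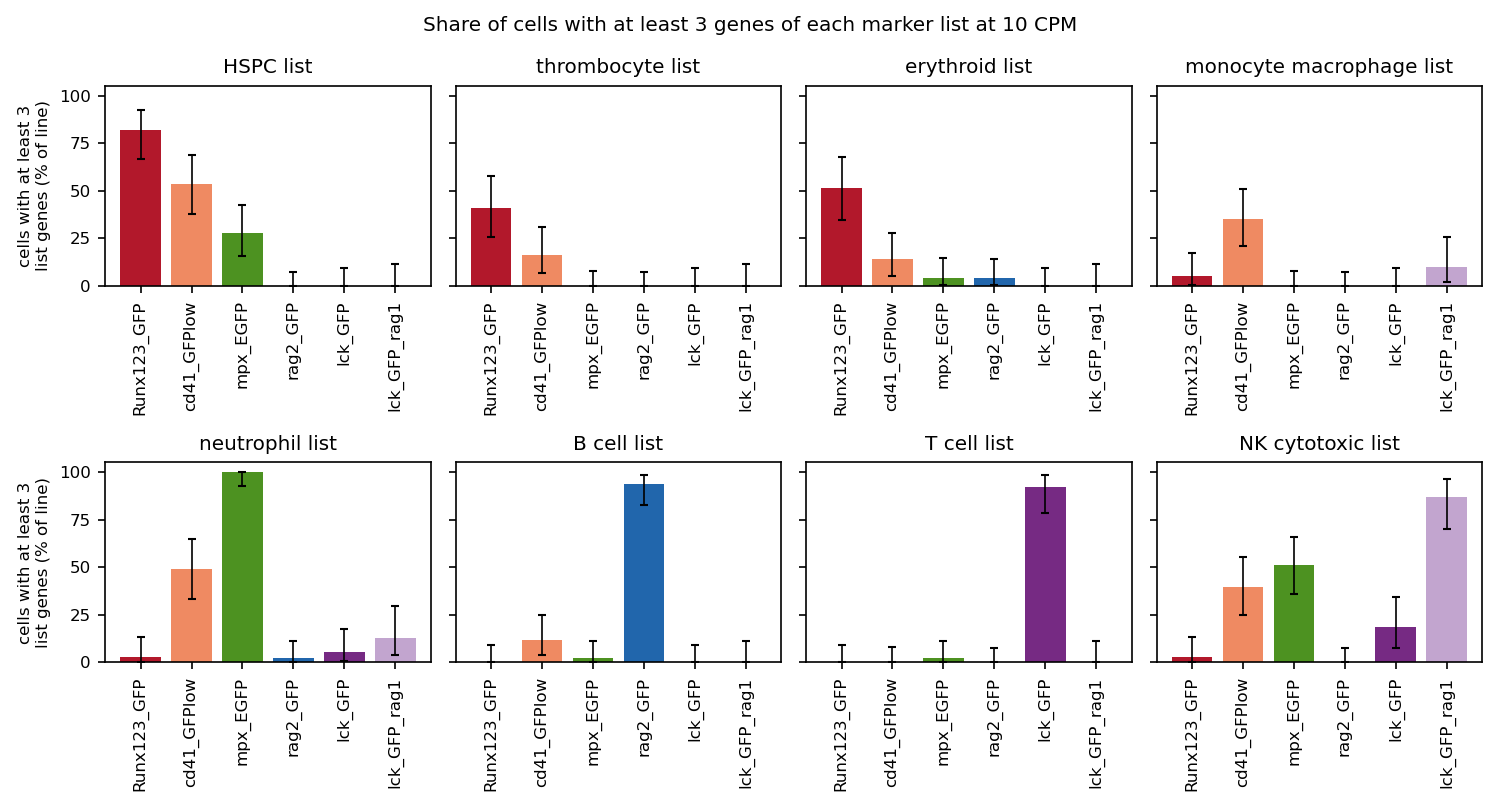
Share of cells of each line (percent, bars) with at least 3 genes of a list at 10 CPM or more, in 1 panel per list, with 95% exact Clopper-Pearson intervals over cells (lines). The highest bars are 100% for neutrophil genes in mpx_EGFP and 93.8% for B cell genes in rag2_GFP.

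Cells with at least 3 cell cycle genes were common in Runx123_GFP and cd41_GFPlow and rare in the lymphoid lines. At least 3 of these genes were present in 28 of 39 Runx123_GFP cells (71.8%; 55.1 to 85%, 72.2% after thinning), 30 of 43 cd41_GFPlow cells (69.8%; 53.9 to 82.8%, 69.8% after thinning) and 15 of 47 mpx_EGFP cells (31.9%; 19.1 to 47.1%, 31.9% after thinning). The lymphoid shares were 6 of 48, 3 of 38 and 2 of 31 cells in rag2_GFP, lck_GFP and lck_GFP_rag1 (14.6%, 9.38% and 6.67% after thinning). Class II genes were present in 29 of 43 cd41_GFPlow cells (67.4%; 51.5 to 80.9%, 67.4% after thinning) and 31 of 48 rag2_GFP cells (64.6%; 49.5 to 77.8%, 65.9% after thinning). Genes shared by T and NK cells were present in 15 of 38 lck_GFP and 15 of 31 lck_GFP_rag1 cells (37.5% and 50% after thinning). Immediate early genes were present in 40 of 47 mpx_EGFP cells (85.1%; 71.7 to 93.8%, 85.1% after thinning) and 20 of 38 lck_GFP cells (52.6%; 35.8 to 69.02%, 46.9% after thinning). No cell of any line had 3 endothelial or eosinophil genes, though only 3 and 4 genes of these lists reached 10 CPM in any summed line. This allows shares of up to 6.25% in rag2_GFP and up to 9.68% in lck_GFP_rag1 (exact upper bounds 7.40% and 11.2%). The kidney tubule and podocyte list and the stroma list each had 1 such cell, in lck_GFP_rag1, and the list for joining of antigen receptor segments had 2, in Runx123_GFP.

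**Figure D3:**
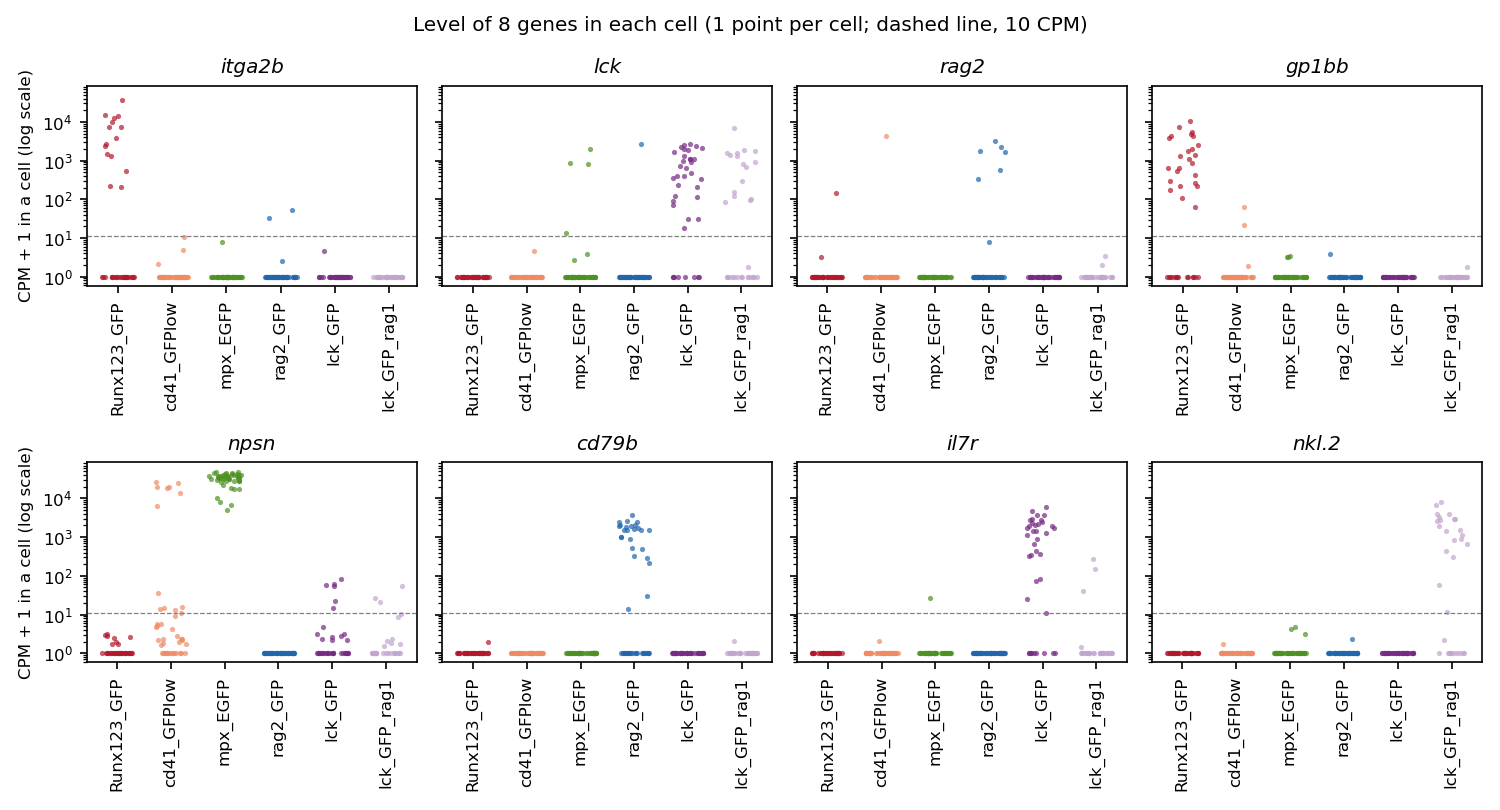
CPM + 1 (log axis) of 8 genes in each of the 246 cells (points) by line, with a dashed line at 10 CPM. The gene npsn lies above the dashed line in all 47 mpx_EGFP cells, and itga2b in 15 of 39 Runx123_GFP and 0 of 43 cd41_GFPlow cells.

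Clustering of all cells gave 10 clusters, of which 9 took a name from the fixed marker lists. The B cell-like cluster held 39 of 48 rag2_GFP cells (81.2%; interval 67.4 to 91.0%), the T cell-like cluster 36 of 38 lck_GFP cells (94.7%; 82.2 to 99.4%) and the NK-like cluster 28 of 31 lck_GFP_rag1 cells (90.3%; 74.2 to 98.0%). A cluster made mostly of 1 line may be that library rather than a cell type. The mpx_EGFP cells split into a pair of neutrophil-like clusters of 30 and 17 cells, and the latter cluster also held 7 cd41_GFPlow cells. Clustering also split uniform groups of simulated cells, so a split of 1 line need not be a difference between kinds of cell. Runx123_GFP cells fell into HSPC-like (14 of 39, 35.9%), erythroid-like (13 of 39, 33.33%) and thrombocyte-like (8 of 39, 20.5%) clusters. The thrombocyte-like share was 38.5% without mitochondrial, ribosomal, cell cycle and immediate early genes. The thrombocyte-like cluster held 0 of 43 cd41_GFPlow cells, which allows up to 6.98% (exact upper bound 8.22%). The cd41_GFPlow cells fell into monocyte-like (16 of 43, 37.2%), HSPC-like (10 of 43, 23.3%), neutrophil-like (7 of 43) and erythroid-like (5 of 43) clusters, and the monocyte-like share was 62.8% at resolution 0.5. HSPC-like as a name was lost in both lines under every alternative clustering except at resolution 2, where 17.9% of Runx123_GFP cells lay in a cluster of that name. The unnamed cluster held 8 rag2_GFP, 4 cd41_GFPlow, 2 lck_GFP_rag1 and 1 Runx123_GFP cells. No caller of doublets was used, since the wells were sorted with 1 cell each, but this does not exclude mixed wells. The gene lck reached 10 CPM in 4 of 47 mpx_EGFP cells, at 12.5, 837, 867 and 2043 CPM. Each of these cells also had npsn, at 22753 CPM or more, and the cause was not tested.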

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

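All alternatives were planned except the removal of cells under 50% uniquely mapped and of each gene's top cell in each line, which were chosen after the results were seen. No paired analysis was possible because the labels name no animals. Of 252 alternative values of the list counts that answer a comparison, 245 stayed within 1.5 times the reported count and 7 did not. With a filter of 50 CPM the higher thrombocyte genes in Runx123_GFP were 5 of 8 against the other lines and 5 of 8 against cd41_GFPlow, because fewer genes were counted, and monocyte and macrophage genes higher in lck_GFP_rag1 than in lck_GFP were 9 in place of 14. That last count was 2 without the deepest cell of each line and 2 without each gene's top cell. Under an 8-fold rule the erythroid genes higher in Runx123_GFP than in cd41_GFPlow were 7 in place of 13. With cells of at least 1000 genes, the T cell genes higher in lck_GFP than in lck_GFP_rag1 were 8 in place of 13, with fewer cells. Of the alternative values of the other list counts, 555 moved and 3477 did not. TMM moved the median gene by -0.21 (log2) in Runx123_GFP, 0.30 in mpx_EGFP, -0.19 in rag2_GFP, 0.12 in lck_GFP_rag1, -0.19 between Runx123_GFP and cd41_GFPlow and 0.24 between lck_GFP and rag2_GFP. DESeq2 moved it by -0.19 in Runx123_GFP, -0.13 in cd41_GFPlow and 0.37 in mpx_EGFP. The 120 named ratios had 1200 alternative values from 1.59 to 14.06, with 0 reversed and 3 under the size rule, though 747 left the narrow counting interval of their ratio and 453 did not.

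Of 70 alternative shares of cells that answer a comparison, 57 lay within the interval of the reported share. Stem and progenitor shares with at least 2 and at least 5 genes were 97.4% and 38.5% in Runx123_GFP (reported 82.1%) and 76.7% and 9.30% in cd41_GFPlow (53.5%). With at least 5 genes the thrombocyte share in Runx123_GFP was 20.5% (41.03%), the neutrophil share in cd41_GFPlow 16.3% (48.8%), the B cell share in rag2_GFP 72.9% (93.8%) and the T cell share in lck_GFP 52.6% (92.1%). With any read the neutrophil share in cd41_GFPlow was 79.1%, and with at least 2 genes the monocyte and macrophage share there was 53.5% (34.9%). The NK share in lck_GFP_rag1 was 96.8% with any read and with at least 2 genes (87.1%). With cells of at least 1000 genes the B cell share in rag2_GFP was 80%. The share in HSPC-like clusters was 0% in both lines at resolution 0.5, with 1000 variable genes, with Ward clustering and without mitochondrial, ribosomal, cell cycle and immediate early genes, and at resolution 2 it was 17.9% in Runx123_GFP (35.9%) and 0% in cd41_GFPlow (23.3%). The monocyte-like share of cd41_GFPlow was 62.8% at resolution 0.5 (37.2%), and without the genes just listed the thrombocyte-like share of Runx123_GFP was 38.5% (20.5%). For these clusters the cause was not tested.

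Of 32 alternative values of the reporter genes, shares of cells and CPM together, 15 left the counting interval of the reported value. All 15 were CPM values, whose intervals are narrow, and no share of cells moved. The only alternative CPM that stayed within its interval was the mean of per-cell CPM of itga2b in cd41_GFPlow, at 0.336. Thinning and the mean of per-cell CPM gave itga2b in Runx123_GFP 2509 and 3014 CPM (1595), lck in lck_GFP 807 and 746 (853), lck in lck_GFP_rag1 648 and 642 (675.0), rag2 in rag2_GFP 244 and 203 (283), rag1 in rag2_GFP 279 and 633 (326), runx1 in Runx123_GFP 2.78 and 1.84 (1.31) and epx in mpx_EGFP 4162 and 4173 (4361). Thinning gave 0 CPM of itga2b in cd41_GFPlow (0.314). The mean weighs each cell alike, so genes of shallow cells rise with it. The number of cells limits a share of 0, which allows up to 6.25% in 48 cells and 9.68% in 31 cells (exact upper bounds 7.40% and 11.2%).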

Other observations

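All tests and contrasts in this part were chosen after the results were seen, and their exact intervals describe the cells of 1 sample per line, not animals.

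The gene itga2b was in 15 of 39 Runx123_GFP cells and 0 of 43 cd41_GFPlow cells. Fewer reads per cell in cd41_GFPlow are excluded, since its median of 1090375 reads lay above the 877541 of Runx123_GFP, and of cells with at least the latter depth 0 of 34 had itga2b (upper bound 10.3%) against 7 of 20 (lower bound 15.4%). A low gate that left out thrombocytes alone may explain it, and this stays open. In the HSPC-like cluster itga2b was in 6 of 14 Runx123_GFP cells (42.9%; 17.7 to 71.1%) and 0 of 10 cd41_GFPlow cells (0 to 30.8%). These intervals overlap, which does not show equal shares, and 42.9% lies above the cd41_GFPlow interval. Nearly all itga2b cells of Runx123_GFP also had the thrombocyte gene gp1bb, at 107.6 to 10603 CPM. The exception had itga2b at 15211 CPM and no gp1bb read. The gene gp1bb was also in some Runx123_GFP cells without itga2b. Most itga2b cells of the HSPC-like cluster thus had a thrombocyte gene too, and do not show itga2b in progenitors alone. The name of this cluster was also lost under most alternative clusterings, so the comparison does not decide. An exchange of labels and a true difference cannot be told apart, because runx1 was in 2 of 39 Runx123_GFP cells (5.13%) and 3 of 43 cd41_GFPlow cells.

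Several light chain genes were present in single rag2_GFP cells, with at least 3 of igic1s1, igl1c3, igl3c3 and igl4c1 in 40 of 48 cells (83.3%). RNA carried over the whole plate is excluded, since 0 of 38 lck_GFP cells on it had any of them (upper bound 9.25%) against 41 of 48 rag2_GFP cells (lower bound 72.2%). RNA carried between rag2_GFP wells alone stays open, because rag2_GFP lay in rows A to D of the plate and lck_GFP in rows E to H. Reads of 1 gene shared among similar copies stay open, since ratios to igic1s1, which led among the 4 genes in 29 of 48 cells, had SDs over cells of 1.12 (0.87 to 1.56), 1.04 (0.83 to 1.41) and 2.22 (1.74 to 3.07) on the log2 scale, and excluding it needed lower bounds over 1. A form revised after that result, with ratios to linc-iglc3, which led among 11 light chain genes with a symbol in 29 of 48 cells, had lower bounds of 0.94, 1.22, 1.46 and 1.41, the smallest also under 1, though each lay above the 0.5 that sharing was expected to stay under. No biological explanation was tested.

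The T cell genes ccr9 or themis were in 10 of 31 lck_GFP_rag1 cells, with both in 0 cells. That all or nearly all of the 10 are T cells is argued against. Another T cell list gene was in 2 of them (upper bound 55.6%) against 35 of 35 such lck_GFP cells (lower bound 90%). Fewer T cells among the 10 stay open. Expression in the NK-like cells themselves stays open, since 9 of the 10 had at least 3 NK and cytotoxic genes (lower bound 55.5%) but so did 18 of the other 21 cells (85.7%). RNA carried from T cells would give the same share, so these shares do not bear on it. Between lck_GFP and lck_GFP_rag1, ccr9 fell from 2817 to 439 CPM and il7r, also abundant in T cells, from 1367 to 8.93 CPM. The genes itk, zap70, cd4-1 and bcl11ba, at 512, 883, 445 and 427.5 CPM in lck_GFP, had no read in lck_GFP_rag1. The T cell list median was 6.47 (log2) higher in lck_GFP. These values argue against carried RNA of an average T cell. The 2 of 10 above argue against RNA of whole single T cells in nearly all of the 10. Carriage of part of a T cell's RNA, or into fewer cells, stays open. Line and plate were the same here, so a plate effect stays open.

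In lck_GFP, cd4-1 or cd4-2.2 was in 13 of 38 cells (34.2%) and cd8a or cd8b in 8 of 38 (21.1%). Both kinds were in 0 of 38 cells, with an exact upper bound of 9.25%, where independence would give 2.74 cells, and neither in 17 of 38. After thinning these were 10, 7 and 0 of 32 cells.

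In rag2_GFP, rag1, rag2 or dntt was in 7 of 48 cells (14.6%). Any of the 4 light chain genes was in 3 of these 7 cells (9.90 to 81.6%) and in 38 of the other 41 (80.1 to 98.5%). The unnamed cluster held 4 of the 7 and 4 of the other 41. At least 3 cell cycle genes were in 4 of 8 rag2_GFP cells of the unnamed cluster and in 2 of 39 of the B cell-like cluster.

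Clustering without mitochondrial, ribosomal, cell cycle and immediate early genes split the mpx_EGFP cells into groups of 30 and 17. At least 3 cell cycle genes were in 3 of 30 (10%; 2.11 to 26.5%) and 12 of 17 cells (70.6%; 44.04 to 89.7%), with the same counts after thinning. Genes that move with the cycle but are not on the list were left in that clustering. Between the groups of 30 and 17, mmp13a was at 4774 and 287.8 CPM, in 28 and 9 cells, and lyz at 13340 and 27020 CPM. The gene npsn was near even, at 32259 and 34178 CPM. These genes were not withheld from that clustering, so their differences are not independent of the split. The main clustering also split uniform simulated groups, so the split alone does not show different kinds of cell.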
